A study of Rattus norvegicus with 10 samples.

How the data were processed

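Polyadenylated RNA from the cortex of the left kidney of male rats was sequenced in 10 libraries, 5 of wild-type and 5 of Kcnj16_m1 genotype, per the labels. The kidneys were flushed with buffered saline under anaesthesia and frozen, and RNA was extracted with Trizol, per the labels' protocols. Those protocols describe both a strand-specific and a strand-unspecific library without saying which was made, so genes overlapping on opposite strands are reported as uncertain. The deposited table gives 1 FPKM value per gene and library, calculated by the authors, with gene symbols, coordinates, lengths and biotypes. Per the submitters' processing notes, fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used. The genome build and the annotation release are not given in the sources used here, and no step of read mapping was repeated. Each column was assigned to its sample by the identifier that the sample's title carries, and the groups were taken from the genotype labels. The labels name no batch, litter or pairing, and replicate numbers only name libraries. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

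Multiplying each FPKM value by the gene length and dividing by 1 step per library gave whole reads for 100% of the values above 0 in every library, within a tolerance of 0.05 reads. These whole reads summed to between 16361516 and 23385968 per library, which is the depth behind the values. The authors' per-million divisor differed from these sums, whose ratio to it ran from 0.921 to 1.02, and median-of-ratios factors over the deposited FPKM lay between 1.00 and 1.01, close to equal in all libraries. No column of per-sample values was left unused. Libraries of 1 group were compared pairwise on the recovered reads. The chi-square per gene lay between 6.91 and 41.8, above the value of 1 that sampling noise alone gives. This argues against repeated sequencing of 1 library, but does not show that the libraries came from separate animals. Each library was counted as 1 sample.

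Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), as the values are not counts. Genes with at least 0.5 FPKM in at least 5 libraries were fitted with a group term, with moderated variances that follow the mean (eBayes with trend=TRUE), and two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The Kcnj16 difference was also tested with an exact permutation test over all 252 splits. Fold changes are Kcnj16_m1 minus SS_WT on the log2 scale, and ± denotes the SD over 5 libraries. The 40 gene lists were written from textbook knowledge before the data were examined and tested with camera (inter-gene correlation preset at 0.01) where at least 4 members were tested, with Benjamini-Hochberg adjustment over lists. They hold 1124 entries, of which 1080 matched a symbol of the table, 6 an older or newer name of the same gene in the RefSeq gene table of assembly GRCr8 and 38 none, and 941 were tested. Where a symbol had several entries, that with the highest mean was used. Beside each list stand the members past the threshold over all genes and those adjusted over the list alone.

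Genes were named by a rule fixed before the data were examined. It takes Kcnj16, then the 10 largest rises and the 10 largest falls in log2 fold change among genes past the threshold with a mean of at least 1 FPKM and groups that do not overlap, and then up to 4 members of each list with the smallest adjusted p. 1263 higher and 1151 lower genes met the conditions for the largest changes, and 0 rises and 2 falls were left out because they had no symbol or a provisional one. The rule names 150 genes, of which 142 passed the threshold. Values of some of these genes are not reported here. Other genes are said to be chosen after their values were seen.

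The fit and the list test were tested on simulated data for Kcnj16_m1 against SS_WT, with reads drawn for the real genes at the real depths and 200 genes changed. A within-group dispersion of 0.03 was assumed first, which 17.4% of the real genes exceed. Among 14045 genes tested, 20.9% of those changed 1.5-fold, 81.8% of those changed 2-fold and 100% of those changed 4-fold were then called in the right direction. Of the calls, 5.73% fell on unchanged genes. After this was seen, the simulation was repeated with the median dispersion of the real genes, 0.00710, which the noisier part of the genes exceeds. Among 14066 genes tested, the shares were then 83.3%, 94.0% and 100%, with 4.02% of the calls on unchanged genes. In these runs small changes of noisy genes were often missed. Far fewer genes were changed there than were called in the real data, which affects the adjusted p. The shares therefore need not hold for the real comparison. In both runs a proximal tubule list raised 1.5-fold was the only list called. The simulated genes varied independently of each other, so the runs cannot show false list calls that come from correlated genes.

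Alternatives fixed before the data were examined were pseudocounts of 1 and 0.1, no filter, a filter at 1 FPKM, rescaling to a sum of 1000000 (TPM), median-of-ratios factors, quantile normalization, eBayes with robust=TRUE or trend=FALSE, library weights, protein-coding genes only, leaving out each library, leaving out the 2 wild-type libraries with the lowest label numbers, an exact rank-sum test, stricter thresholds, and camera with an estimated correlation, fry and camera on ranks. Removing a trend on gene length, keeping genes of at least 1000 bases and limma-voom on the recovered reads were added after seeing the data. Metabolite measurements named in the series title were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.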

Results

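Transcript levels were measured by RNA sequencing in the cortex of the left kidney of male rats aged 11 to 12 weeks. All were on the background of the Dahl salt-sensitive (SS) rat, an inbred line that becomes hypertensive on salt. The 10 libraries formed 2 groups, wild type (SS_WT, n = 5) and mutant for Kcnj16 (Kcnj16_m1, n = 5), the gene of an inward-rectifier potassium channel subunit of the kidney tubule. The table lists 32545 genes, of which 21459 were above 0 FPKM (fragments per kilobase of gene per 1000000 fragments) in at least 1 library. The per-million divisor was the authors' own and differed from the recovered reads of the libraries. The whole reads behind the values came to 16818886, 16749487, 16778605, 16863579 and 16541364 in wild-type replicates 1 to 5. In mutant replicates 1 to 5 they came to 23385968, 17007143, 19262042, 21044507 and 16361516. The first principal component of the 13971 tested genes held 39.2% of the variance and separated the groups. The wild-type libraries lay between -34.3 and -8.47 on it and the mutants between 20.5 and 24.2.

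The mutated gene was examined first. Kcnj16 (ENSRNOG00000004713) lies on chromosome 10, 99388130 to 99389898, plus strand. These and the other coordinates are those of the deposited table, whose genome build is not given in the sources used here. Kcnj16 stood at 343, 372, 323, 366 and 329 FPKM in wild-type replicates 1 to 5 and at 307, 327, 339, 338 and 319.9 FPKM in mutant replicates 1 to 5. The log2 fold change was -0.09, with a 95% interval from -0.21 to 0.04, and did not pass (exact two-sided permutation p = 0.127 over 252 splits, limma adjusted p = 0.278). The transcript was present in every library, and since a mutation need not remove it, its level cannot check the genotype labels.

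The comparison of the groups asks which cortical transcripts differ between Kcnj16_m1 and wild-type rats. Of the 13971 genes tested, 2033 were higher and 1955 lower in the mutants, together 28.5% (limma, Benjamini-Hochberg adjusted p under 0.05). By a log2 fold change of at least 1, 72 genes rose and 205 fell. The values of the groups did not overlap for 2686 genes, which is 19.2% of those tested, against 0.794% by chance. At an adjusted p under 0.01 the counts were 873 higher and 964 lower. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values.

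Among the 10 largest rises was that of the kallikrein family gene Klk1c2. Klk1c2 went from 1.39 ± 0.953 to 34.6 ± 8.46 FPKM (SD, n = 5 per group for these and all later values, log2 fold change 4.41, SE 0.42, adjusted p = 0.000129). Its relatives Klk1c10 and Klk1c6 rose by log2 fold changes of 2.85 and 2.23. Reads can be misassigned between these near-identical copies, so the value of each copy is uncertain. Ptgs2, the inducible cyclooxygenase gene, rose from 1.20 ± 0.0456 to 4.30 ± 0.331 FPKM (log2 fold change 1.495, SE 0.07, adjusted p = 1.47e-06). Slc2a4, which encodes the insulin-responsive glucose transporter, rose from 0.868 ± 0.216 to 3.38 ± 0.335 FPKM. Others of the 10 largest rises were those of Ubap1l, the acyl-CoA thioesterase gene Acot5, the glucuronosyltransferase gene Ugt2a1 and the carboxylesterase gene Ces1d. Their log2 fold changes were 2.45, 1.64, 1.64 and 1.54. Acot5, Ugt2a1 and Ces1d belong to families of close copies, and the last 2 overlap a neighbour, so their values are uncertain too.

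Havcr1, which encodes the tubular injury marker kidney injury molecule, had the largest fall on the log2(FPKM + 0.5) scale. The ratio of mutant to wild-type mean was lower for Il19 (0.00613) than for Havcr1 (0.0169). Il19 stood at 0 FPKM in mutant replicates 2, 3 and 5 and at 0.0822 and 0.0918 FPKM in mutant replicates 1 and 4, so its ratio rests on few reads. Havcr1 went from 21.7 ± 13.6 to 0.367 ± 0.147 FPKM (log2 fold change -4.44, SE 0.40, adjusted p = 0.000101), and lies on chromosome 10, 31813814 to 31848379, plus strand. Its values ran from 5.85 to 42.3 FPKM in wild type and from 0.196 to 0.521 FPKM in mutants. Spp1, which encodes osteopontin, fell from 1407 ± 863 to 111 ± 20.6 FPKM (log2 fold change -3.42, SE 0.41, adjusted p = 0.000392). Lcn2, which encodes the injury marker lipocalin, fell from 23.2 ± 14.5 to 1.88 ± 0.475 FPKM (log2 fold change -3.09, SE 0.41, adjusted p = 0.000670). The complement gene C4b fell from 13.8 ± 7.52 to 0.791 ± 0.219 FPKM, but overlaps its near-identical copy C4a, so its value is uncertain. The complement regulator gene Cfi fell from 10.8 ± 7.25 to 1.29 ± 0.394 FPKM. The rest of the 10 largest falls were those of the cytokine gene Il19, the carbonic anhydrase gene Car3, the ubiquitin-like gene Ubd, the lectin gene Reg3g and Angptl7. Their log2 fold changes were -3.31, -2.85, -2.55, -2.47 and -2.43. Angptl7 overlaps Mtor and is uncertain.

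**Figure D1:**
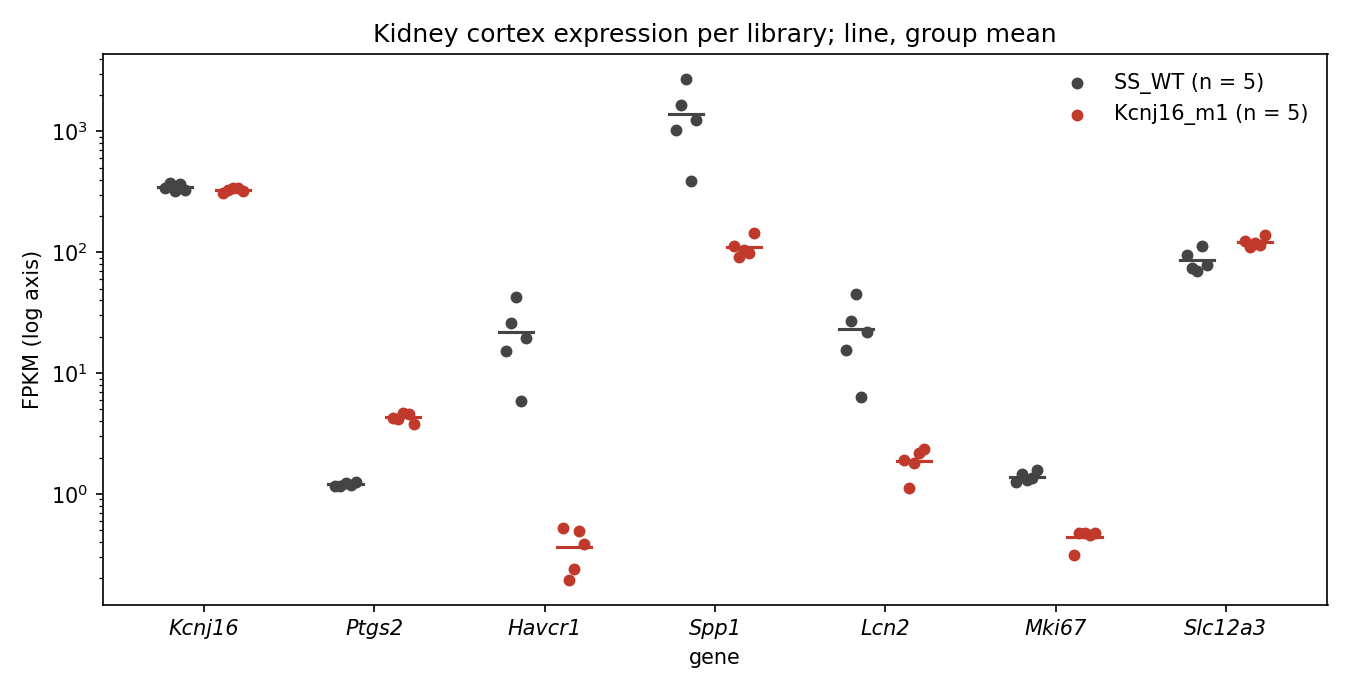
FPKM of 7 genes on a log axis in the 5 SS_WT and 5 Kcnj16_m1 libraries, 1 point per library, with a line at the group mean. Havcr1 runs from 5.85 to 42.3 FPKM in wild type and from 0.196 to 0.521 FPKM in the mutants, while the points of Kcnj16 overlap.

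Genes of tubular injury and dedifferentiation were mostly lower in the mutants. On this list 2 of 38 tested members were higher, 25 lower and 11 did not pass, with 2 higher and 26 lower adjusted over the list alone. The list had a median log2 fold change of -0.61 (camera adjusted p = 1.18e-08, adjusted p = 0.333 with an estimated correlation). Havcr1, Spp1 and Lcn2 belong to it, and so does the adhesion receptor gene Cd44, which fell from 8.93 ± 3.98 to 1.78 ± 0.384 FPKM (log2 fold change -1.95, SE 0.28, adjusted p = 0.00106). In wild type, replicate 3 had the highest and replicate 4 the lowest values of Havcr1, Spp1 and Lcn2. Over the members of the injury, cytokine, cell division, macrophage and lymphocyte lists, the median excess over the mutants was 0.45, 0.61, 0.80, 0.32 and 0.63 on the log2 scale in wild-type replicates 1 to 5. In the extracellular matrix list 4 of 36 tested members were higher, 13 lower and 19 did not pass, with 4 higher and 14 lower adjusted over the list alone. Matrix genes had a median log2 fold change of -0.27 (camera adjusted p = 0.000529, adjusted p = 0.488 with an estimated correlation). Fn1, which encodes fibronectin, fell from 11.8 ± 3.54 to 4.42 ± 0.507 FPKM and Col1a1 from 13.0 ± 2.64 to 5.72 ± 1.21 FPKM. The proteoglycan gene Dcn fell from 119 ± 39.5 to 52.4 ± 5.88 FPKM, and Col5a2 fell by 0.71 on the log2 scale. Of the unfolded protein response genes, 1 of 24 tested members were higher, 9 lower and 14 did not pass, with 1 higher and 9 lower adjusted over the list alone. These genes had a median log2 fold change of -0.32 (camera adjusted p = 0.000529, adjusted p = 0.480 with an estimated correlation). The median was -0.18 without the 2 wild-type libraries with the lowest label numbers. The stress transcription factor gene Atf3 fell by 1.15, the asparagine synthetase gene Asns fell by 0.80, Pdia4 fell by 0.73 and Dnajc3 fell by 0.42 on the log2 scale.

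Among macrophage and dendritic cell markers, 0 of 22 tested members were higher, 17 lower and 5 did not pass, with 0 higher and 17 lower adjusted over the list alone. Macrophage markers had a median log2 fold change of -0.64 (camera adjusted p = 9.41e-09, adjusted p = 0.333 with an estimated correlation). Tyrobp, a myeloid signalling adaptor gene, fell from 31.4 ± 6.76 to 17.8 ± 0.963 FPKM and Laptm5 from 14.7 ± 2.87 to 7.78 ± 0.818 FPKM. Trem2 fell from 2.43 ± 1.12 to 0.550 ± 0.0664 FPKM and Flt3 from 1.299 ± 0.178 to 0.431 ± 0.101 FPKM. Of T, B and NK cell markers, 0 of 14 tested members were higher, 10 lower and 4 did not pass, with 0 higher and 11 lower adjusted over the list alone. Lymphocyte markers had a median log2 fold change of -0.77 (camera adjusted p = 6.35e-06, adjusted p = 0.333 with an estimated correlation). With no filter the median was -0.32. The pan-leukocyte gene Ptprc fell from 5.62 ± 1.24 to 2.85 ± 0.421 FPKM and the T cell gene Lck from 2.43 ± 0.598 to 0.948 ± 0.104 FPKM. Cd3g fell from 2.69 ± 0.558 to 0.546 ± 0.575 FPKM and Igj, whose product joins immunoglobulin chains, from 3.97 ± 0.822 to 1.77 ± 0.228 FPKM. In the cytokine and interferon list, 0 of 42 tested members were higher, 19 lower and 23 did not pass, with 1 higher and 23 lower adjusted over the list alone. Cytokine and interferon genes had a median log2 fold change of -0.41 (camera adjusted p = 3.77e-08, adjusted p = 0.394 with an estimated correlation). The chemokine genes Cxcl11, Ccl2 and Cxcl16 and the transcription factor gene Irf8 had log2 fold changes of -1.44, -0.83, -0.48 and -0.83. Cxcl11 and Cxcl16 each overlap another gene and are uncertain. The neutrophil and mast cell list had a single tested member, Fcgr3a, which alone cannot stand for these cells. It overlaps Fcgr2b, is uncertain and had a log2 fold change of -0.57. Its adjusted p was 0.0231, and 0.0505 without mutant replicate 2.

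Of the cell division genes, 0 of 26 tested members were higher, 21 lower and 5 did not pass, with 0 higher and 21 lower adjusted over the list alone. Cell division genes had a median log2 fold change of -0.76 (camera adjusted p = 2.85e-11, adjusted p = 0.333 with an estimated correlation). Mki67, a marker of cycling cells, fell from 1.39 ± 0.131 to 0.437 ± 0.0701 FPKM (log2 fold change -1.01, SE 0.10, adjusted p = 0.000160). Top2a fell from 1.66 ± 0.296 to 0.545 ± 0.0806 FPKM, the kinesin gene Kif11 from 20.5 ± 2.20 to 11.7 ± 0.781 FPKM and the replication licensing gene Mcm4 from 3.40 ± 0.177 to 2.12 ± 0.102 FPKM. In the immediate early list, 2 of 24 tested members were higher, 6 lower and 16 did not pass, with 2 higher and 7 lower adjusted over the list alone. Immediate early genes had a median log2 fold change of -0.20 (camera adjusted p = 0.105, adjusted p = 0.623 with an estimated correlation). Their median ran from -0.21 to -0.09 over the alternatives. Egr2, Junb and Klf2 had log2 fold changes of -1.02, -0.74 and 0.55, with adjusted p = 0.00110, 0.00443 and 0.0107. Without the 2 wild-type libraries with the lowest label numbers, the adjusted p of Klf2 was 0.0575.

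**Figure D2:**
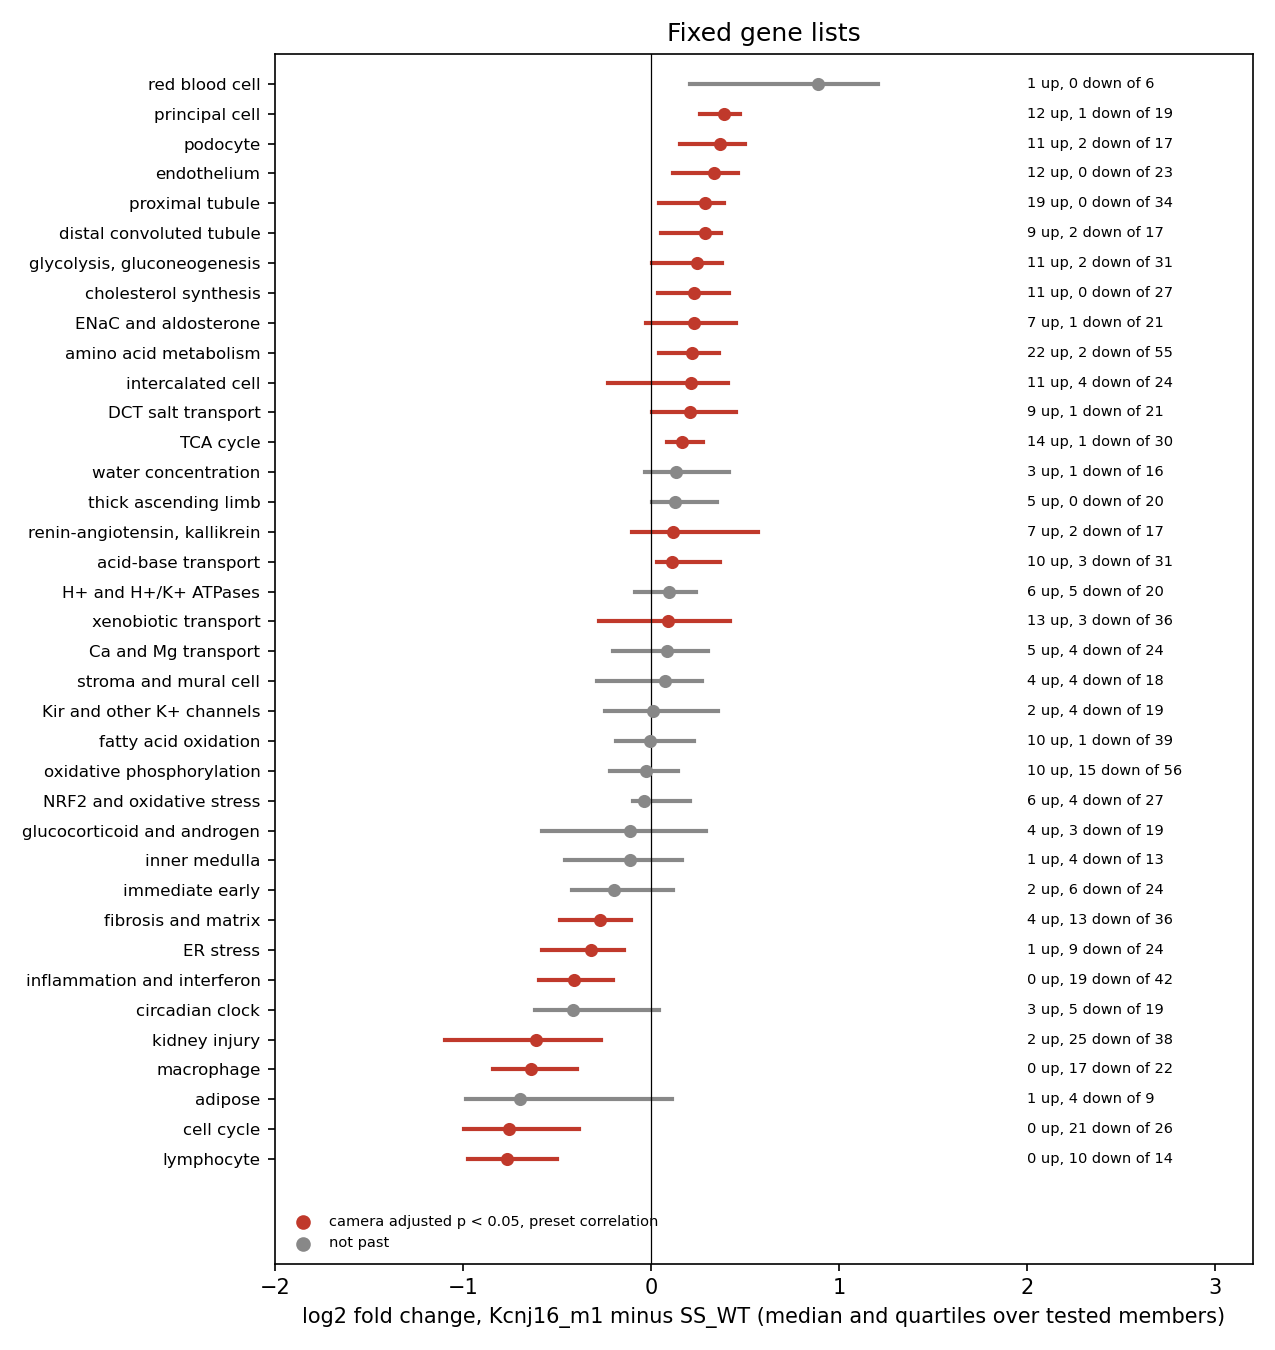
Median (point) and quartiles (line) of the log2 fold change, Kcnj16_m1 minus SS_WT, over the tested members of 37 gene lists, with the numbers of members higher and lower at the right. Lists past camera's adjusted p of 0.05 with the preset correlation are red, and lymphocyte markers have the lowest median (-0.77).

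Members of the renin-angiotensin and kallikrein list went both ways. On it 7 of 17 tested members were higher, 2 lower and 8 did not pass, with 7 higher and 2 lower adjusted over the list alone. The list had a median log2 fold change of 0.12 (camera adjusted p = 0.0306, adjusted p = 0.333 with an estimated correlation). Klk1c2 and Ptgs2 rose among them. Ace, which encodes angiotensin-converting enzyme, fell from 0.782 ± 0.124 to 0.264 ± 0.0389 FPKM (log2 fold change -0.74, SE 0.11, adjusted p = 0.00130). In the sodium chloride transport list of the distal convoluted tubule, 9 of 21 tested members were higher, 1 lower and 11 did not pass, with 10 higher and 2 lower adjusted over the list alone. This list had a median log2 fold change of 0.21 (camera adjusted p = 0.0226, adjusted p = 0.488 with an estimated correlation). The chloride channel subunit gene Bsnd rose from 17.1 ± 2.37 to 23.5 ± 2.01 FPKM (log2 fold change 0.45, SE 0.09, adjusted p = 0.00572). Klhl3, which controls WNK kinase degradation, rose from 6.15 ± 1.71 to 9.99 ± 1.07 FPKM. Among epithelial sodium channel genes and mineralocorticoid receptor targets, 7 of 21 tested members were higher, 1 lower and 13 did not pass, with 9 higher and 1 lower adjusted over the list alone. Sodium channel and mineralocorticoid genes had a median log2 fold change of 0.23 (camera adjusted p = 0.0181, adjusted p = 0.488 with an estimated correlation). Ndrg2 rose from 11.1 ± 1.06 to 23.8 ± 2.11 FPKM (log2 fold change 1.08, SE 0.08, adjusted p = 3.73e-05). The protease gene Tmprss2 rose from 37.0 ± 3.38 to 50.6 ± 1.77 FPKM and Fxyd4, a regulator of the sodium pump, from 4.64 ± 1.24 to 8.86 ± 1.09 FPKM. Slc26a4, which encodes the chloride-bicarbonate exchanger pendrin, fell from 20.2 ± 3.75 to 9.88 ± 0.769 FPKM (log2 fold change -0.98, SE 0.11, adjusted p = 0.000317). Chosen after its values were seen, the aldosterone-induced kinase gene Sgk1 rose from 55.0 ± 16.6 to 139.9 ± 56.9 FPKM (log2 fold change 1.29, SE 0.30, adjusted p = 0.00978). Scnn1b and Scnn1g, also chosen after their values were seen, had log2 fold changes of 0.34 and 0.43 (adjusted p = 0.00501 and 0.0160), and Scnn1b overlaps Cog7 and is uncertain. The camera adjusted p of the renin-angiotensin list was 0.0505 without wild-type replicate 3, 0.114 on ranks, 0.120 for genes of at least 1000 bases and 0.0556 with the length trend removed (0.00550 to 0.333 over the camera alternatives). That of the sodium channel list was 0.0560 without wild-type replicate 3 (0.00319 to 0.488 over the camera alternatives). The median of this list was 0.34 without wild-type replicate 4 and 0.36 without mutant replicate 1, and ran from 0.16 to 0.36 over the alternatives. The camera adjusted p of the sodium chloride list was 0.0696 with quantile normalization (0.00286 to 0.488 over the camera alternatives). Its median was 0.13 without wild-type replicate 3 and 0.13 without mutant replicate 5.

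Potassium channel genes went both ways. Of them, 2 of 19 tested members were higher, 4 lower and 13 did not pass, with 5 higher and 4 lower adjusted over the list alone. Their median log2 fold change was 0.010 and their mean -0.017 (camera adjusted p = 0.987, adjusted p = 0.986 with an estimated correlation), and the median ran from -0.02 to 0.32 over the alternatives. Kcne5, Kcnj3, Kcnk1 and Kcnn4 fell by 1.49, 0.49, 0.44 and 0.64 on the log2 scale. Chosen after its values were seen, Kcnj10, whose product pairs with that of Kcnj16, stood at 9.62 ± 2.81 FPKM in wild type and 13.4 ± 1.90 FPKM in mutants (adjusted p = 0.0633). In the acid-base list, 10 of 31 tested members were higher, 3 lower and 18 did not pass, with 12 higher and 3 lower adjusted over the list alone. Acid-base genes had a median log2 fold change of 0.11 (camera adjusted p = 0.00780, adjusted p = 0.480 with an estimated correlation). The amino acid transporter gene Slc6a19 rose from 67.0 ± 7.61 to 110.0 ± 4.57 FPKM (log2 fold change 0.72, SE 0.07, adjusted p = 0.000198). The anion exchanger genes Slc4a1 and Slc4a9 rose from 27.9 ± 5.12 to 48.8 ± 3.13 FPKM and from 17.1 ± 3.34 to 27.0 ± 1.64 FPKM, opposite to Slc26a4. Slc4a1 is also a red blood cell marker. Among proton and potassium pump genes, 6 of 20 tested members were higher, 5 lower and 9 did not pass, with 6 higher and 5 lower adjusted over the list alone. Pump genes had a median log2 fold change of 0.09 (camera adjusted p = 0.371, adjusted p = 0.766 with an estimated correlation). The median ran from 0.06 to 0.15 over the alternatives. Atp6v1c2 and Atp6v1b1 had log2 fold changes of 0.63 and 0.51, and Atp6v1g3 and Atp6v1d of -0.61 and -0.38.

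In the calcium and magnesium transport list, 5 of 24 tested members were higher, 4 lower and 15 did not pass, with 5 higher and 4 lower adjusted over the list alone. Its genes had a median log2 fold change of 0.09 (camera adjusted p = 0.638, adjusted p = 0.787 with an estimated correlation). The parathyroid hormone receptor gene Pth1r rose from 217 ± 17.5 to 277 ± 12.5 FPKM and Cnnm2 from 16.0 ± 1.91 to 20.2 ± 1.62 FPKM. The calcium channel gene Trpv5 fell from 5.22 ± 1.32 to 3.04 ± 0.499 FPKM and Slc41a1 from 6.21 ± 0.434 to 4.63 ± 0.409 FPKM. Of the genes of urine concentration and osmolytes, 3 of 16 tested members were higher, 1 lower and 12 did not pass, with 3 higher and 1 lower adjusted over the list alone. Urine concentration genes had a median log2 fold change of 0.13 (camera adjusted p = 0.0789, adjusted p = 0.333 with an estimated correlation). The median ran from 0.08 to 0.19 over the alternatives, and by fry the adjusted p was 0.00107. Avpr2, which encodes the vasopressin receptor of the collecting duct, rose from 8.28 ± 1.44 to 13.7 ± 0.922 FPKM. The water channel gene Aqp3 rose from 50.6 ± 6.15 to 68.8 ± 4.83 FPKM and Creb3l1 from 2.50 ± 0.411 to 5.04 ± 0.580 FPKM. Elf3 had a log2 fold change of -0.44 with adjusted p = 0.0166, and 0.0805 without the 2 wild-type libraries with the lowest label numbers.

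In amino acid metabolism, 22 of 55 tested members were higher, 2 lower and 31 did not pass, with 29 higher and 5 lower adjusted over the list alone. Amino acid genes had a median log2 fold change of 0.22 (camera adjusted p = 3.27e-05, adjusted p = 0.480 with an estimated correlation). The serine synthesis genes Psph and Psat1 rose from 37.1 ± 5.89 to 70.7 ± 2.33 FPKM and from 89.0 ± 13.7 to 140.2 ± 6.88 FPKM. Prodh, which starts proline breakdown, rose from 9.99 ± 2.27 to 23.9 ± 3.08 FPKM and Acmsd, of tryptophan breakdown, from 133 ± 23.6 to 251 ± 6.58 FPKM. Of the genes of pyruvate dehydrogenase and the tricarboxylic acid cycle, 14 of 30 tested members were higher, 1 lower and 15 did not pass, with 15 higher and 2 lower adjusted over the list alone. Tricarboxylic acid cycle genes had a median log2 fold change of 0.17 (camera adjusted p = 0.000389, adjusted p = 0.474 with an estimated correlation). The malic enzyme gene Me1 rose from 32.3 ± 4.90 to 52.0 ± 4.59 FPKM. The isocitrate dehydrogenase genes Idh3g and Idh2 rose by log2 fold changes of 0.51 and 0.48, while the kinase gene Pdk3, an inhibitor of pyruvate dehydrogenase, fell by 0.42. In glycolysis and gluconeogenesis, 11 of 31 tested members were higher, 2 lower and 18 did not pass, with 12 higher and 4 lower adjusted over the list alone. Glycolysis and gluconeogenesis genes had a median log2 fold change of 0.25 (camera adjusted p = 0.00428, adjusted p = 0.474 with an estimated correlation). Pc, which encodes pyruvate carboxylase, rose from 121 ± 14.7 to 226 ± 12.7 FPKM (log2 fold change 0.91, SE 0.08, adjusted p = 0.000107). The gluconeogenic gene Fbp1 rose from 859 ± 63.3 to 1106 ± 60.9 FPKM. The glycolytic genes Eno1 and Pgk1 rose from 779.5 ± 89.5 to 1057 ± 32.8 FPKM and from 259 ± 38.7 to 360.3 ± 19.9 FPKM. Pc and Idh2 each overlap another gene and are uncertain.

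Of the cholesterol synthesis genes, 11 of 27 tested members were higher, 0 lower and 16 did not pass, with 12 higher and 1 lower adjusted over the list alone. Cholesterol synthesis genes had a median log2 fold change of 0.23 (camera adjusted p = 0.00214, adjusted p = 0.480 with an estimated correlation). Dhcr7, of the last step of the pathway, rose from 9.51 ± 0.365 to 17.2 ± 1.83 FPKM. The desaturase gene Scd2 rose from 17.1 ± 1.77 to 35.6 ± 5.90 FPKM. The lipogenic transcription factor gene Srebf1, which overlaps Rai1 and is uncertain, rose from 9.09 ± 1.49 to 16.7 ± 3.52 FPKM. In fatty acid oxidation, 10 of 39 tested members were higher, 1 lower and 28 did not pass, with 10 higher and 2 lower adjusted over the list alone. The median log2 fold change was -0.006 and the mean 0.01, with an upward direction by camera (adjusted p = 0.232, adjusted p = 0.726 with an estimated correlation). The median was 0.00902 with TPM scaling and ran from -0.06 to 0.05 over the alternatives. The acyl-CoA synthetase genes Acsm3, Acsm5 and Acsm1 rose by log2 fold changes of 0.87, 1.08 and 0.41, and the thiolase gene Acaa1a by 0.70. Acsm3 and Acsm1 overlap other genes and are uncertain. Of the respiratory chain genes, 10 of 56 tested members were higher, 15 lower and 31 did not pass, with 10 higher and 16 lower adjusted over the list alone. Respiratory chain genes had a median log2 fold change of -0.03 (camera adjusted p = 0.166, adjusted p = 0.766 with an estimated correlation). The median was 0.05 with the length trend removed and 0.07 for genes of at least 1000 bases, and the camera adjusted p was 0.0353 without wild-type replicate 3 (0.0353 to 0.766 over the camera alternatives). Atp5l, Ndufc2, Atp5j2 and Cox6c fell by 0.43, 0.40, 0.50 and 0.36 on the log2 scale. Their listed lengths are 477, 560, 419 and 448 bases, and over all tested genes under 500 bases 152 were lower and 58 higher.

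In the list of organic ion transport and conjugation, 13 of 36 tested members were higher, 3 lower and 20 did not pass, with 15 higher and 4 lower adjusted over the list alone. Organic ion genes had a median log2 fold change of 0.09 (camera adjusted p = 0.0430, adjusted p = 0.474 with an estimated correlation). The efflux pump gene Abcc4 rose from 16.9 ± 1.22 to 27.2 ± 1.57 FPKM, while Abcb1a, another efflux pump gene, fell from 2.08 ± 0.279 to 1.15 ± 0.122 FPKM. The urate transporter genes Slc22a12 and Slc17a3 rose from 148 ± 19.0 to 231 ± 20.2 FPKM and from 52.1 ± 4.20 to 78.9 ± 8.22 FPKM. Without wild-type replicate 3 the camera adjusted p of this list was 0.257. It was 0.0788, 0.0507 and 0.0639 without wild-type replicate 1, mutant replicate 1 and mutant replicate 2 (0.0280 to 0.474 over the camera alternatives). A filter at 1 FPKM gave 0.0536, trend=FALSE 0.0507, library weights 0.0779, removal of the length trend 0.0627, genes of at least 1000 bases 0.0800 and camera on ranks 0.0756. The median was 0.15 without wild-type replicate 3 and 0.14 without the 2 wild-type libraries with the lowest label numbers. In the oxidative stress list, 6 of 27 tested members were higher, 4 lower and 17 did not pass, with 7 higher and 5 lower adjusted over the list alone. Oxidative stress genes had a median log2 fold change of -0.03 (camera adjusted p = 0.767, adjusted p = 0.883 with an estimated correlation). The sign of this median differs from camera's direction, which was upward, and the median was 0.00223 with quantile normalization and ran from -0.07 to 0.15 over the alternatives. Gpx2 fell from 18.0 ± 9.75 to 3.94 ± 0.775 FPKM (log2 fold change -1.92, SE 0.29, adjusted p = 0.00126). The NADPH oxidase gene Cybb, which phagocytes express, fell from 14.1 ± 2.51 to 8.73 ± 0.827 FPKM. Akr7a3 rose from 350.0 ± 58.8 to 630.3 ± 124 FPKM and the glutathione reductase gene Gsr from 146 ± 19.6 to 199.5 ± 8.49 FPKM. Gsr overlaps a small nucleolar RNA gene on the opposite strand and is uncertain.

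Among proximal tubule markers, 19 of 34 tested members were higher, 0 lower and 15 did not pass, with 23 higher and 0 lower adjusted over the list alone. Proximal tubule markers had a median log2 fold change of 0.29 (camera adjusted p = 7.77e-06, adjusted p = 0.369 with an estimated correlation). Slc6a19, Slc17a3 and Slc22a12 rose among them. Of the distal convoluted tubule markers, 9 of 17 tested members were higher, 2 lower and 6 did not pass, with 9 higher and 2 lower adjusted over the list alone. Distal convoluted tubule markers had a median log2 fold change of 0.29 (camera adjusted p = 0.0194, adjusted p = 0.488 with an estimated correlation). Slc12a3, which encodes the thiazide-sensitive sodium chloride cotransporter, rose from 86.0 ± 17.7 to 121 ± 11.0 FPKM (log2 fold change 0.51, SE 0.12, adjusted p = 0.0109). Sall3 rose from 1.38 ± 0.242 to 2.48 ± 0.153 FPKM. Among principal cell markers, 12 of 19 tested members were higher, 1 lower and 6 did not pass, with 13 higher and 1 lower adjusted over the list alone. Principal cell markers had a median log2 fold change of 0.39 (camera adjusted p = 0.000105, adjusted p = 0.394 with an estimated correlation). Mal rose from 53.3 ± 4.01 to 69.9 ± 1.42 FPKM and the ammonia channel gene Rhcg from 48.2 ± 7.89 to 69.8 ± 2.88 FPKM. Intercalated cell markers went both ways, and 11 of 24 tested members were higher, 4 lower and 9 did not pass, with 12 higher and 4 lower adjusted over the list alone. Intercalated cell markers had a median log2 fold change of 0.21 (camera adjusted p = 0.0357, adjusted p = 0.489 with an estimated correlation). Slc26a4 and Atp6v1g3 fell among them, and Slc4a1 and Atp6v1c2 rose. Without wild-type replicate 3 the camera adjusted p was 0.0505 for the distal convoluted tubule (0.00279 to 0.488 over the camera alternatives) and 0.0505 for intercalated cells (0.00653 to 0.489 over the camera alternatives). For intercalated cells it was 0.0658, 0.0661 and 0.0507 without wild-type replicates 2 and 5 and mutant replicate 5. It was 0.0578 with a filter at 1 FPKM, 0.0568 with quantile normalization, 0.0556 with the length trend removed and 0.0899 without the 2 wild-type libraries with the lowest label numbers.

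Of podocyte markers, 11 of 17 tested members were higher, 2 lower and 4 did not pass, with 11 higher and 2 lower adjusted over the list alone. Podocyte markers had a median log2 fold change of 0.37 (camera adjusted p = 0.000348, adjusted p = 0.333 with an estimated correlation). Nphs1, which encodes nephrin, rose from 9.51 ± 1.15 to 14.5 ± 1.11 FPKM and Wt1 from 4.71 ± 0.630 to 7.96 ± 1.04 FPKM. Ptpro rose from 9.43 ± 0.449 to 14.5 ± 0.863 FPKM and Npr3 from 6.48 ± 0.621 to 9.04 ± 0.802 FPKM. Of endothelial markers, 12 of 23 tested members were higher, 0 lower and 11 did not pass, with 14 higher and 0 lower adjusted over the list alone. Endothelial markers had a median log2 fold change of 0.33 (camera adjusted p = 4.93e-05, adjusted p = 0.333 with an estimated correlation). The vascular growth factor receptor gene Kdr rose from 10.3 ± 1.26 to 16.4 ± 0.874 FPKM (log2 fold change 0.66, SE 0.08, adjusted p = 0.000492). Ehd3 rose from 12.6 ± 1.66 to 22.04 ± 3.04 FPKM, Sox17 from 2.53 ± 0.200 to 3.66 ± 0.283 FPKM and Plat from 26.6 ± 3.13 to 37.0 ± 1.84 FPKM. Among thick ascending limb markers, 5 of 20 tested members were higher, 0 lower and 15 did not pass, with 5 higher and 0 lower adjusted over the list alone. Thick ascending limb markers had a median log2 fold change of 0.13 (camera adjusted p = 0.0528, adjusted p = 0.625 with an estimated correlation). Without wild-type replicates 1 and 4 and mutant replicates 3 and 4 in turn, the camera adjusted p was 0.0326, 0.0127, 0.0435 and 0.0413 (0.0127 to 0.625 over the camera alternatives). With no filter, a filter at 1 FPKM, TPM scaling, quantile normalization and limma-voom it was 0.0209, 0.0422, 0.0371, 0.0490 and 0.0447, and 0.0306 without the 2 wild-type libraries with the lowest label numbers. The median ran from 0.05 to 0.20 over the alternatives. Sostdc1 rose from 37.3 ± 8.39 to 63.1 ± 6.63 FPKM and Cyfip2 from 13.3 ± 2.92 to 20.7 ± 1.21 FPKM. Cldn10 rose from 76.6 ± 9.83 to 96.3 ± 8.30 FPKM, with adjusted p = 0.0515 and 0.0514 without mutant replicates 4 and 5. Of fibroblast and mural cell markers, 4 of 18 tested members were higher, 4 lower and 10 did not pass, with 4 higher and 4 lower adjusted over the list alone. Fibroblast and mural cell markers had a median log2 fold change of 0.08 (camera adjusted p = 0.822, adjusted p = 0.950 with an estimated correlation). Their median ran from -0.04 to 0.18 over the alternatives. Col3a1 fell by 0.84 on the log2 scale, and Col1a1 and Dcn fell among them.

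Markers of other tissues were examined in the same libraries. For red blood cells, 1 of 6 tested members were higher, 0 lower and 5 did not pass, with 1 higher and 0 lower adjusted over the list alone. Red blood cell markers had a median log2 fold change of 0.89 (camera adjusted p = 0.0789, adjusted p = 0.394 with an estimated correlation). The member that rose was Slc4a1, which is also on the acid-base and intercalated cell lists. The haemoglobin genes Hba1, Hba2 and Hbb, which have close copies, stood at 48.6 ± 24.3, 17.5 ± 10.1 and 22.7 ± 10.2 FPKM in wild type. In mutants they stood at 119.5 ± 62.8, 45.9 ± 25.97 and 45.8 ± 22.4 FPKM (adjusted p = 0.0656, 0.0814 and 0.107). Without mutant replicate 5 these adjusted p were 0.0272, 0.0289 and 0.0343, and that of the list 0.0371. With all libraries kept, that of the list was 0.00422 with no filter, 0.00746 with TPM scaling (0.00422 to 0.394 over the camera alternatives) and 0.00804 by fry. That of Hba1 was 0.0451 with the length trend removed and 0.0471 with limma-voom. For adipose tissue, 1 of 9 tested members were higher, 4 lower and 4 did not pass, with 1 higher and 5 lower adjusted over the list alone. Adipose markers had a median log2 fold change of -0.69 (camera adjusted p = 0.10, adjusted p = 0.480 with an estimated correlation). The median was -0.36 with TPM scaling, -0.04 with a filter at 1 FPKM, -0.01 with no filter and 0.04 for genes of at least 1000 bases. By fry the list passed (adjusted p = 0.0172), and by camera the adjusted p ran from 0.0770 to 0.797 over the alternatives. Fabp4 fell from 8.40 ± 3.06 to 1.38 ± 0.462 FPKM, Cidea fell by 0.99 on the log2 scale, and Lpl rose from 11.6 ± 3.02 to 23.2 ± 2.19 FPKM. For the inner medulla, 1 of 13 tested members were higher, 4 lower and 8 did not pass, with 3 higher and 4 lower adjusted over the list alone. Inner medulla markers had a median log2 fold change of -0.11 (camera adjusted p = 0.390, adjusted p = 0.489 with an estimated correlation). The median ran from -0.18 to 0.05 over the alternatives, and by fry the list passed (adjusted p = 0.0424). S100a4, Krt7, Krt19 and Epha7 had log2 fold changes of -1.21, -0.24, -0.54 and 0.53. Krt7 and Krt19 are also on the tubular injury list. The adjusted p of Krt19 was 0.0532, 0.0519 and 0.0507 without wild-type replicates 2 and 5 and mutant replicate 5. Without the 2 wild-type libraries with the lowest label numbers it was 0.106 for Krt19, 0.0790 for Krt7 and 0.0596 for Epha7. Adrenal and muscle markers had 3 tested members each, too few for the list test. The adrenal markers Fdx1 and Cyp11a1 had log2 fold changes of 0.20 and 0.53 (adjusted p = 0.0201 and 0.0266). The adjusted p of Cyp11a1 was 0.0641 and 0.0586 without wild-type replicates 2 and 5. It was 0.0525, 0.0586 and 0.0623 without mutant replicates 1, 3 and 4, and 0.107 without the 2 wild-type libraries with the lowest label numbers. Mrap, Des, Tnnt3 and Mylpf had adjusted p = 0.356, 0.104, 0.756 and 0.861. For Mrap it was 0.0143 without wild-type replicate 3, and for Des 0.0331 without wild-type replicate 4.

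Circadian clock genes changed in both directions. Of these, 3 of 19 tested members were higher, 5 lower and 11 did not pass, with 3 higher and 5 lower adjusted over the list alone. Clock genes had a median log2 fold change of -0.42 (camera adjusted p = 0.166, adjusted p = 0.625 with an estimated correlation). Without mutant replicate 5 the camera adjusted p was 0.0349 (0.0349 to 0.625 over the camera alternatives). The clock activator gene Arntl rose from 1.45 ± 0.931 to 5.24 ± 2.18 FPKM (log2 fold change 1.57, SE 0.33, adjusted p = 0.00610), Npas2 from 1.14 ± 0.729 to 3.74 ± 0.934 FPKM and Clock from 9.91 ± 0.929 to 14.4 ± 0.940 FPKM. The repressor gene Cry1 fell from 2.45 ± 0.645 to 1.21 ± 0.297 FPKM. The time of day of collection was not used here. Of glucocorticoid and androgen responsive genes, 4 of 19 tested members were higher, 3 lower and 12 did not pass, with 4 higher and 3 lower adjusted over the list alone. Hormone responsive genes had a median log2 fold change of -0.11 (camera adjusted p = 0.692, adjusted p = 0.825 with an estimated correlation). Their median ran from -0.14 to 0.12 over the alternatives. The metallothionein genes Mt1 and Mt2A, which have close copies, fell from 2148 ± 372 to 973 ± 60.0 FPKM and from 3164 ± 1023 to 1218 ± 59.3 FPKM. Hsd17b11 rose from 46.0 ± 8.26 to 65.2 ± 2.55 FPKM.

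Of the 37 lists tested, 22 passed camera with the preset correlation, 15 higher and 7 lower in the mutants. None passed with an estimated correlation, where the lowest adjusted p was 0.333 and 2 lists had an unadjusted p under 0.05. By fry, which tests a list's own genes without comparing them with other genes, 26 lists passed. In 5 of 100 splits of the libraries into groups of 5, the real one included, at least 22 lists passed, so chance is not excluded for the number of lists.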

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

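The tests of the wild-type replicate 1 excess, of the list medians over splits and of the members of the 5 lists were chosen after the results were seen.

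A library far from the other 4 of its group, by the gap to its neighbour over the group's range, was seen in 19 of the 292 sets of 5 values examined (the named genes and the recovered reads in each group), where chance gives about 14.6. In wild-type replicate 3 this held for Ndrg2 (9.23 FPKM, others 11.2 to 12.0), Atf3 (5.66 FPKM, others 2.77 to 3.21), Kif11 (24.4 FPKM, others 19.2 to 20.04), Mrap (5.19 FPKM, others 11.1 to 13.5) and Fabp4 (13.7 FPKM, others 6.32 to 8.08). In mutant replicate 5 this held for Srebf1 (22.9 FPKM, others 14.6 to 16.4), Klf2 (27.7 FPKM, others 38.1 to 42.3) and Wt1 (6.17 FPKM, others 7.97 to 8.67). In wild-type replicate 4 this held for Angptl7 (7.84 FPKM, others 4.53 to 5.45), Acsm5 (7.20 FPKM, others 5.12 to 5.58) and Wt1 (5.81 FPKM, others 4.23 to 4.63). In mutant replicate 1 this held for Mki67 (0.312 FPKM, others 0.456 to 0.474) and Tyrobp (16.1 FPKM, others 18.1 to 18.5). In mutant replicate 2 this held for Pth1r (255 FPKM, others 281 to 285) and Cd3g (1.53 FPKM, others 0 to 0.422). In mutant replicate 3 this held for Trpv5 (3.90 FPKM, others 2.63 to 2.97). In mutant replicate 4 this held for Acmsd (263 FPKM, others 247 to 249). In wild-type replicate 2 this held for Sox17 (2.18 FPKM, others 2.57 to 2.66). In wild-type replicate 5 this held for Slc17a3 (59.4 FPKM, others 49.2 to 51.1).

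The splits drawn argue against chance for the number of genes, but cannot exclude it. The real grouping gave 3988 genes, and the highest of the other splits of the 10 libraries gave 3, so 1 of 100 splits drawn, the real one, gave as many. For the number of lists chance cannot be excluded, as the real grouping gave 22, the highest other split 23, and 5 of 100 splits gave at least as many. In 17 of the 100 splits, the real one included, at least 19 of the lists were called, and the cause was not tested. Every other split kept 3 or 4 of the wild-type libraries on 1 side, so part of the group difference stayed in it. Taking the size of each list's median log2 fold change in place of the camera call, no other split drawn matched the real one for 14 of the 22 lists changed. These 22 lists were picked by their calls in the real split, which favours a large real median. Adipose markers, which were not called, were not matched either (-0.69, largest other 0.440 in size). For kidney injury the real median was -0.61 and the largest other 0.509 in size, for cell division -0.76 and 0.524, for macrophages -0.64 and 0.556, and for lymphocytes -0.77 and 0.573. The cytokine and interferon median of -0.41 was matched by another split (0.440 in size), so that 2 of 100 splits were as large, the real one included. For the other matched lists these numbers were 28 (organic ion transport), 11 (renin-angiotensin), 8 (matrix), 5 (sodium channel and mineralocorticoid), 4 (unfolded protein response), 4 (acid-base) and 2 (cholesterol synthesis).

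The lower level of kidney injury, cytokine, cell division, macrophage and lymphocyte genes in the mutants is a pattern to follow up, with 89 of the 137 tested members of these 5 lists lower and 2 higher. The tables argue against a single wild-type library, since 5 of the 5 lists were called lower by camera with the preset correlation without each of the 10 libraries in turn (with all libraries kept, none passed with an estimated correlation, adjusted p = 0.333 to 0.394), with 69 to 89 members lower. They argue against a gene length trend between libraries as the whole cause, since removing it left 101% of the median log2 fold change of the members (-0.57 before and -0.57 after). Against a library difference that sets wild-type replicates 2 to 5 apart stands the median excess of replicate 1 over the mutants (0.45), which was 72.5% of the median of the other wild-type libraries and above that of replicate 4 (0.32), but 1 library excludes nothing and it stays open. An effect of the genotype may account for the pattern, but it stays a hypothesis that these libraries cannot separate from an unlabelled batch.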

How the results depend on the processing

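The length trend, the length minimum of 1000 bases and limma-voom were chosen after the data were seen, and the other alternatives before. The Kcnj16 difference stayed negative and short of the threshold in each alternative run, from -0.11 to -0.06 without 1 library. Without 1 library, the number of genes changed ran from 3013 to 4476, with 1516 to 2364 higher and 1473 to 2112 lower, and the number of lists from 18 to 23. The lowest number of lists came without wild-type replicate 3, the lowest number of genes without wild-type replicate 2. The counts moved by over 1.5 times only at an adjusted p under 0.01 (1837 genes, 873 higher and 964 lower) and with an absolute log2 fold change of at least 1 (277 genes, 72 higher and 205 lower), where the stricter threshold itself is the cause, and for lists with an estimated correlation (0 lists), where the cause was not tested. The exact rank-sum test called 2686 genes, which is the number of genes whose groups do not overlap, so it is no separate support for the count. With limma-voom on the recovered reads 4144 genes were called, of which 3868 were called in the same direction by the FPKM test. The fit without the 2 wild-type libraries with the lowest label numbers called 3654. With another scaling the share of higher calls went from 51.0% to 55.2% (TPM) and 54.6% (quantile normalization), and the median of all genes was at most 0.0214. TPM scaling also changed which genes were tested, 14759 in place of 13971, so scaling is not the only change there. Median-of-ratios factors were nearly equal between libraries and so tested little. Of the 142 named genes past the threshold, 134 passed in each alternative where they were tested and 8 were lost in at least 1, and 0 results reversed. Genes that reach 0.5 FPKM only in wild type, such as Il19, Reg3g and Mki67, fail the filter without a wild-type library. They were not tested there, and 135 of the 142 were tested without wild-type replicate 1. The median of 2 of 37 lists, fatty acid oxidation and oxidative stress, changed sign under a scaling. Of the 22 lists past camera, 16 were called in each alternative that kept camera's preset correlation. Depth limits low genes most, where a gene near 0.5 FPKM rests on few reads and its fold change is understated by the pseudocount.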

Other observations

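The gene families, the genes named with them, the clock and kallikrein tests and the library comparison by gene length in this part were chosen after the data were seen. Among 35 families defined by gene symbol, 18 passed camera with the preset correlation and none with an estimated one (lowest adjusted p = 0.131 with an estimated correlation). The families named here kept the sign of their median with TPM scaling, median-of-ratios factors and quantile normalization. Cytosolic ribosomal protein genes had 5 of 102 higher and 40 lower (median log2 fold change -0.21, camera adjusted p = 1.20e-06, adjusted p = 0.312 with an estimated correlation); many are short and have near-identical pseudogenes. Complement genes had 0 of 18 higher and 10 lower (median log2 fold change -0.65, camera adjusted p = 0.000142, adjusted p = 0.312 with an estimated correlation), with C1qa falling from 44.9 ± 7.45 to 25.8 ± 4.09 FPKM, and major histocompatibility genes 0 of 22 higher and 9 lower (median log2 fold change -0.26, camera adjusted p = 0.00152, adjusted p = 0.312 with an estimated correlation), with RT1-Ba falling from 44.9 ± 8.45 to 27.3 ± 3.36 FPKM. Glutathione S-transferases had 9 of 15 higher and 2 lower (median log2 fold change 0.47, camera adjusted p = 0.00277, adjusted p = 0.312 with an estimated correlation). Of these Gstm7 rose from 23.7 ± 2.16 to 65.0 ± 3.59 FPKM and Gstm1 from 41.8 ± 19.4 to 98.4 ± 4.35 FPKM, but they have close copies and Gstm7 overlaps Gstm3, so their values are uncertain. Aldehyde dehydrogenases had 8 of 13 higher and 1 lower (median log2 fold change 0.27, camera adjusted p = 0.00284, adjusted p = 0.131 with an estimated correlation), led by the retinoic acid enzyme gene Aldh1a1, which rose from 211 ± 19.8 to 365 ± 15.3 FPKM. HOX genes had 7 of 20 higher and 0 lower (median log2 fold change 0.24, camera adjusted p = 0.00702, adjusted p = 0.131 with an estimated correlation), among them Hoxb2 and Hoxb6, which rose from 15.2 ± 1.08 to 22.4 ± 2.26 FPKM and from 26.5 ± 0.816 to 38.4 ± 4.52 FPKM. The interleukin family had 0 of 14 higher and 9 lower (median log2 fold change -0.53, camera adjusted p = 0.00152, adjusted p = 0.227 with an estimated correlation), and the alarmin gene Il33 fell from 68.4 ± 4.19 to 45.7 ± 4.97 FPKM.

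Calls differed with gene length. Of 1056 tested genes under 500 bases, 58 were higher and 152 lower, and of 7674 genes of 2000 bases or more, 1291 were higher and 801 lower. Counting genes for which 4 wild-type libraries lay beyond all mutants on 1 side and the remaining wild-type library did not, the odd library was wild-type replicate 1 for 80 genes under 500 bases, against 14, 18, 21 and 14 for wild-type replicates 2 to 5. For genes of 2000 bases or more these numbers were 533, 97, 241, 438 and 116 for wild-type replicates 1 to 5.

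Clock genes offer a second pattern. Arntl, Npas2 and Clock had a median log2 fold change of 1.43, and 7 targets of their product (Dbp, Tef, Hlf, Per2, Per3, Ciart and Bhlhe41) -0.72, a difference of 2.15. Of these targets Hlf, Per3, Ciart and Bhlhe41 passed the threshold and Dbp, Tef and Per2 did not (adjusted p = 0.0746, 0.115 and 0.193). Mutant replicate 5 stood apart, with Dbp at 159.9 FPKM against 56.9, 57.6, 92.3 and 82.8 in mutant replicates 1 to 4. It lay within the wild-type range for all 7 targets, Arntl and Npas2, but not for Clock (13.0 FPKM, wild type 9.05 to 11.1). By label number it stands next to wild-type replicates 4 and 5, apart from mutant replicates 1 to 4. Wild-type replicate 3 had Dbp at 86.8 FPKM. It lay within the range of mutant replicates 1 to 4 for Dbp, Tef, Hlf, Per2 and Per3, but not for Ciart and Bhlhe41. A candidate explanation is a difference in the time of day of collection. It cannot be told apart from an effect of the mutation on the clock. No collection time was used here, and both predict activators and targets moving apart. Mutant replicate 5 and wild-type replicate 3 bear on this question, but 2 libraries cannot decide it.

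The rise of Klk1c2, Klk1c10 and Klk1c6 could come from reads moved between near-identical kallikrein copies. A move among copies of similar length leaves the sum of their FPKM nearly unchanged. The FPKM summed over the 7 Klk1c genes was 164 ± 26.7 in wild type and 303 ± 18.5 in mutants (SD, n = 5 each), a ratio of 1.85. The lowest mutant stood at 284 and the highest wild-type library at 198 FPKM (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 can give). Klk1c9, which overlaps a neighbour and is uncertain, made up most of the sum and rose from 161 ± 25.9 to 258 ± 22.2 FPKM. The test argues against moves among these 7 genes as the whole cause, if their lengths are similar. It does not cover reads exchanged with genes outside them, and which copy rose stays open.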
